A study of Mus musculus with 16 samples.

How the data were processed

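Genomic DNA from the tails of 8 C57BL/6 mice of 1 family was compared with the DNA of 1 reference male of the same colony by array comparative genomic hybridisation, in which 2 DNAs labelled with the dyes Cy3 and Cy5 compete for the same probes and the ratio of their signals reports relative copy number. The family held a sire, a dam and 6 offspring, and each mouse was hybridised on 2 arrays with the dyes exchanged, giving 16 arrays. Per the labels, the arrays were a second screen: a first array had been used to pick candidate probes, and probes were placed densely around those candidates for this family. The regions covered were therefore chosen by an earlier screen of the family, so that counts of regions describe these stretches and not the genome.

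The deposited scanner files hold the intensity of each spot in each channel. Per the file headers they were written by Agilent Feature Extraction 10.7.1.1 with the protocol CGH_107_Sep09, on probes placed on build mm9, and their processed intensities are already background-subtracted and scaled by a linear dye factor. Each array held 170574 spots, of which 6563 were controls. The 164011 other spots carried 159978 probes, 1024 of them on more than 1 spot. The log10 ratio column of the deposited scanner files was made by the scanner software as the log10 of Cy5 over Cy3 processed intensities, and it was used only to check those intensities. The deposited value table holds log2 ratios of the same arrays with no stated scale or direction. Set against the scanner values, each of its columns followed the log2 ratio of reference over mouse, with slopes of 0.94 to 1.00 on log2(Cy5/Cy3) where the mouse was in Cy3 and of -0.99 to -0.94 where it was in Cy5, and with column medians from -0.0026 to 0.0125. Its centring was thus close to 0, and the step that separates it from the scanner ratios is not given in the sources used here. It lacked 689 values and was used only as an alternative.

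From the processed intensities, log2(mouse/reference) was computed for each spot, turned the same way on every array, and centred on the array's median over non-control spots. Non-uniform outlier spots were left out, spots of 1 probe were averaged, probes missing on any array were dropped, and the 2 orientations of a mouse were averaged into 1 value, so that a mouse counts as 1 replicate. This left 159628 autosomal probes, 48 probes on X and 3 on Y. Calls were made on autosomes, a choice made after the small number of X and Y probes had been seen.

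Each mouse's profile was divided along each chromosome by penalised least squares, with segments of at least 5 probes and a penalty of 3 times the log of the number of probes times the noise variance. A segment was called where its median was at least 0.3 in size in the mean of both orientations and at least 0.15, with the same sign, in each. Calls of different mice sharing at least 50% of the probes of the shorter were joined into 1 region. Its core was the probes present in 50% or more of its calls, and a mouse carried the region where its median over the core passed the same thresholds. Regions carried by offspring with both parents under 0.15 in size were counted apart from those with a parent at 0.15 or more in size that did not pass the thresholds, called undecided here. False calls were gauged in part by segmenting the difference of the orientations divided by 2, in which the mouse's own signal cancels. Probes were also shuffled within chromosomes. Removal of the dye bias common to all mice from that difference, and shuffling without the shifted blocks, were added after these counts had been seen. Transmission of regions carried by exactly 1 parent was tested against 50% with an exact two-sided binomial test, which treats all regions as independent, linked ones included.

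Probe-wise fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), for the mean of the 8 mice against 0 and for offspring minus parents. The mice are relatives measured against 1 reference animal, so p-values measure the spread between these mice only. The arrays lay on 4 slides of 4 arrays. The sire and the dam shared 1 slide and the offspring filled the other 3, so that generation and slide cannot be separated; slide as a random block takes account of slide differences among the offspring only in part. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

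The calling was tested on simulated data with independent noise: every implanted segment of 5, 10 or 50 probes at a shift of 0.4, 0.6 or 1.0 was recovered with 0 false calls, and the segmentation equalled an exhaustive search in 50 of 50 short series. Over 159628 simulated probes, limma recovered 96.5% of 200 probes shifted by 0.3 in all mice, with 5 false calls. It recovered 87.0% of 200 probes shifted by 0.5 in the offspring, with 11 false calls. Noise shared by neighbouring probes or by mice was not simulated.

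Added after the data had been seen, tiled blocks were defined as probes with starts no more than 2 kb apart. Blocks of at least 10 probes whose median reached 0.2 in size in any mouse were joined into loci within 1 Mb. Alternatives, listed before the data were examined unless marked as added, were normexp background correction (offset 50), loess within arrays, the deposited value table, removal of dim or saturated probes, thresholds of 0.2 and 0.5, at least 3 or 10 probes, penalties of 2 and 6, each orientation alone, runs of 5 probes past the threshold in both orientations, joining calls at 1 shared probe, leaving out each mouse, slide as a random block, and arrays kept apart with the mouse as a random block and a dye term. The normexp step used median spot and background intensities, since the scanner files hold no mean intensities. Correlations for random blocks were estimated on 20000 probes. A correction for base composition and a test of gene groups were not run: no genome sequence was used here, the files give positions without gene names, and the gene table at hand belongs to another build. Regions are therefore given by mm9 position only. By a rule fixed before the data were examined, the regions named are those carried by offspring and neither parent and those carried by a parent and no offspring (the 10 largest of each where there were more) and the 15 largest of the rest; others are named as chosen after their values were seen.

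The number of arrays, 2 per mouse, limits the precision. Median raw intensities ran from 490 to 879.5 in Cy3 over median backgrounds of 37 to 43, and from 729 to 1204 in Cy5 over 69 to 74. Between 0.176% and 0.291% of spots per array were not well above background in a channel, and 0 were saturated. The noise of the orientation mean between neighbouring probes was 0.051 to 0.060 (SD, log2) per mouse.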

Results

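The series followed 1 mouse family in a study of fathers exposed to continuous gamma-rays at 1 mGy per day for 400 days, and asked which DNA copy-number changes appear in the progeny. The series title describes the males as exposed, while the design text calls the sire of this family non-irradiated, so its exposure is not settled here. No unexposed family was part of the data, and the comparisons below are within the family. DNA of the sire, the dam and their 6 offspring was hybridised against 1 reference male on 16 arrays, 2 per mouse with the dyes exchanged. A value per mouse has no replicate animal behind it, and its error is given as the values of both orientations or the SD over probes. A single added copy over 2 gives a log2 ratio of 0.58 in an ideal measurement and a single lost copy gives -1. The 159628 autosomal probes formed 5912 blocks of any size. Of these, 1800 were tiled blocks of at least 10 probes, with a median of 108 probes over 11.2 kb, and 3961 were isolated probes.

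Segmentation called 267 segments in the 8 mice, which fell into 146 regions, and scoring every mouse at each region gave 286 carrier states. The dam had the most calls with 98, of which 96 were losses. Offspring 2 had 46 calls, offspring 1 had 34, offspring 5 had 32, offspring 6 had 30, the sire had 12, offspring 3 had 11 and offspring 4 had 4. When the mouse signal was cancelled by taking the difference between orientations, 72 segments still passed 0.3, and 14 did once the dye bias common to all mice was removed. Shuffled probes gave 3 calls once the shifted blocks had been left out, and 176 with them in. Shuffling removes noise shared by neighbouring probes, and the difference between orientations cancels noise shared by both arrays of a mouse. Segments of that difference also had no rule for each orientation to pass. None of these counts is therefore a rate of false calls among the 267 segments. Without the dam, chosen as the mouse with the most calls after the data had been seen, 73 regions and 178 carrier states remained.

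The regions were of 2 kinds. At the level of whole tiled blocks, 21 of 1800 blocks were shifted by at least 0.2 in any mouse, and they formed 6 loci on chromosomes 2, 3, 4, 8 and 14. These loci held 24 of the 146 regions. The other 122 regions were short, with 5 to 13 probes, a median span of 436 bp and a longest span of 1711 bp, and 120 of them had fewer than 10 probes. Block medians outside the 6 loci reached at most 0.17 in size in any mouse, where the definition of the loci allows less than 0.2, and their robust SD was 0.012 to 0.028 per mouse.

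**Figure D1:**
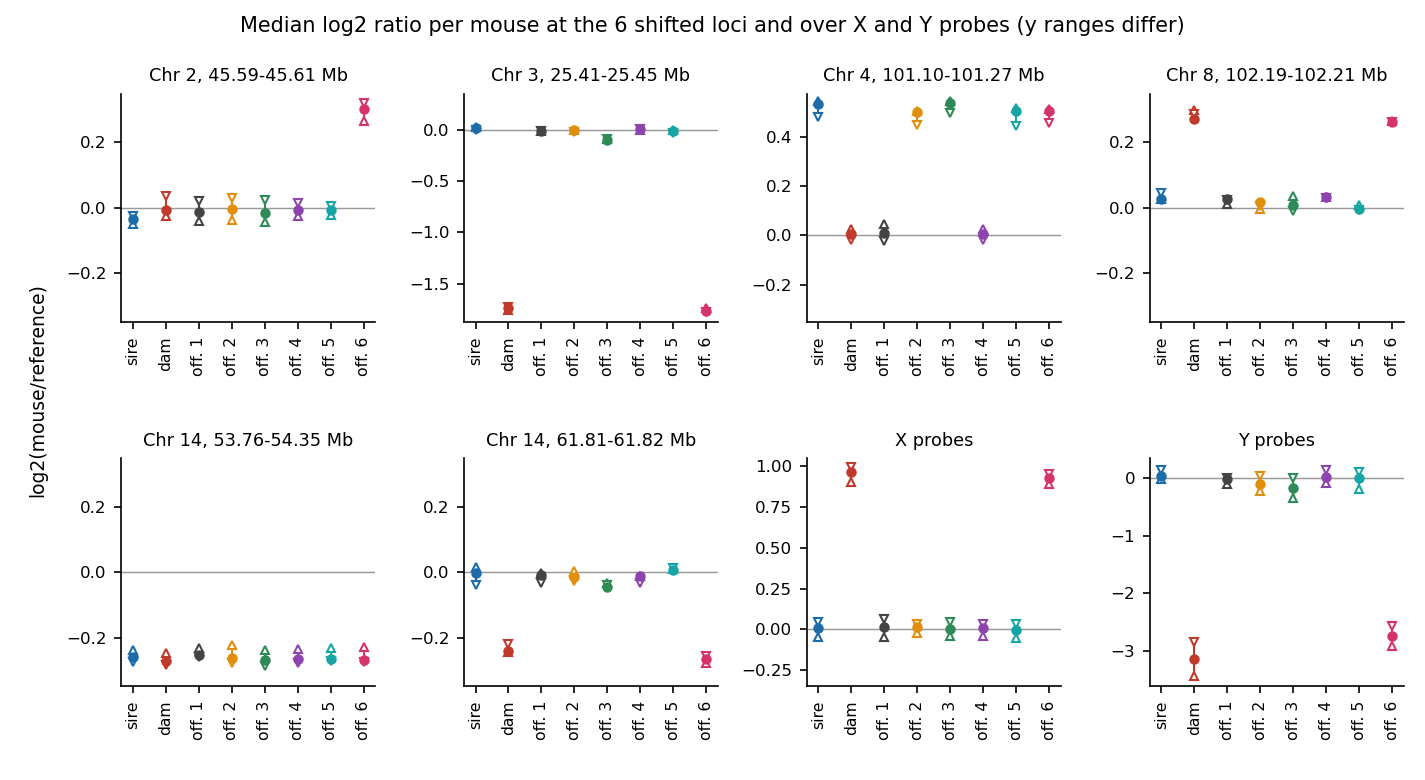
Median log2(mouse/reference) of each mouse (x axis) at the 6 shifted loci and over the X and Y probes, with y ranges that differ between panels. Filled circles are the mean of both orientations, upward triangles the array with the mouse in Cy5 and downward triangles the array with the mouse in Cy3; the chromosome 4 locus sits at 0.50 to 0.54 in 5 mice and at 0.00 to 0.01 in the other 3.

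The comparison of the parents with their offspring asked which copy-number states were passed on. The sire carried a gain on chromosome 4 that 4 of the 6 offspring also carried. It was called as 3 adjacent regions between 101109089 and 101270967, and as 1 region of 161.9 kb and 1337 probes when segments needed at least 10 probes. The median log2 ratio over the locus was 0.53 in the sire, 0.50 in offspring 2, 0.54 in offspring 3, 0.50 in offspring 5 and 0.50 in offspring 6, with SDs over probes of 0.15 to 0.17. The dam, offspring 1 and offspring 4 lay between 0.00 and 0.01. Both orientations gave the gain in each carrier, from 0.45 to 0.55. Probes ending at 101109049 and starting at 101270969 flanked the gain, which placed both ends inside tiled blocks.

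**Figure D2:**
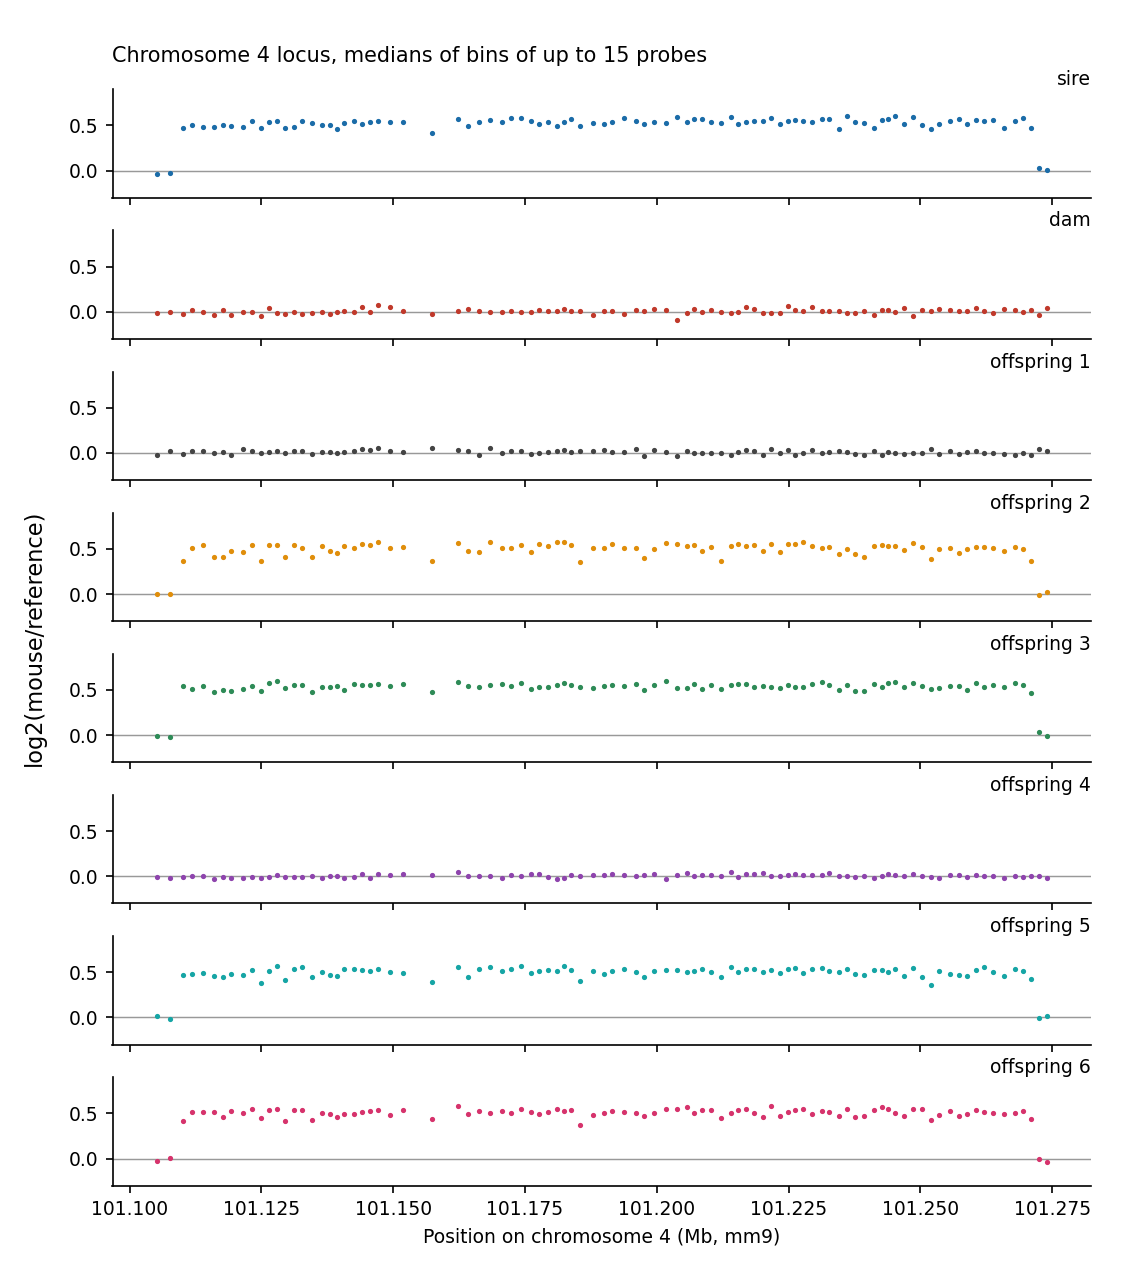
Log2(mouse/reference) along the chromosome 4 locus (x axis, position in Mb on mm9), 1 panel per mouse, each point the median of a bin of up to 15 probes. The sire and offspring 2, 3, 5 and 6 step up to about 0.5 between 101109089 and 101270967, while the dam and offspring 1 and 4 stay near 0.

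The dam and offspring 6 shared a deep loss on chromosome 3 from 25416456 to 25449872, covering 132 probes. Its median was -2.03 in the dam and -1.999 in offspring 6, and between -0.02 and 0.01 in the sire and offspring 1, 2, 4 and 5. Offspring 3 lay at -0.12, with -0.10 and -0.15 in its orientations. The same pair of mice shared 3 further shifts. The X and Y probes below set the same pair apart, so this sharing is not read here as transmission. On chromosome 8, from 102186717 to 102206071, the block medians were 0.27 in the dam and 0.26 in offspring 6 against -0.01 to 0.03 in the other 6 mice. On chromosome 14, from 61810472 to 61821192, they were -0.24 in the dam and -0.27 in offspring 6 against -0.05 to 0.01 in the others. A region of 6 probes on chromosome 2, from 111694136 to 111694677, was at -0.86 in the dam and -0.996 in offspring 6 and between -0.02 and 0.06 elsewhere.

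The X and Y probes, read beside the labels, separated the same mice. Over 48 X probes the median was 0.96 in the labelled dam (SD over probes 0.12) and 0.01 in the labelled sire. Offspring 6 was at 0.93 and the other offspring were between -0.01 and 0.01. Over 3 Y probes the medians were -3.15 in the dam, -2.75 in offspring 6 and 0.04 in the sire, and the single probes ran from -4.96 to -0.84 in the dam and from -4.81 to -0.42 in offspring 6. In an ideal measurement, 2 copies over 1 in the reference give a log2 ratio of 1. Offspring 6 thus had X and Y ratios like those of the labelled dam, and the other offspring had ratios near the labelled sire's. The labels used here give no sex for the offspring, and no mice were grouped by these values.

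Of the 146 regions, 31 were carried by a parent and at least 1 offspring, 75 by a parent and no offspring, 3 by all 8 mice, 24 by offspring with a parent at 0.15 or more in size that was no carrier, and 11 by offspring with both parents below 0.15. In 2 regions no mouse passed the core threshold. Of the 75 regions seen in a parent alone, 71 were short losses of the dam. The named ones ran from -0.66 at 69996671 to 69997049 on chromosome 18 to -0.48 at 67849404 to 67849676 on chromosome 11, each over 5 probes. Offspring 6 was above 0 at each of the 8 short dam losses that the rule names. The dam's SDs over probes at these 8 ran from 0.345 to 0.661, so the probes of a loss differed widely. The loss at 63643500 to 63644019 on chromosome 10, at -0.52 with an SD over probes of 0.49, was -0.14 under normexp. A gain of the sire alone lay on chromosome 7 at 47256759 to 47257330 with 0.48 over 9 probes, an SD over probes of 0.46, and 0.02 under normexp. A gain of 0.49 in the dam over 6 probes at 54169067 to 54172134 on chromosome 14 was -0.02 under normexp.

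Among 103 regions carried by exactly 1 parent, the offspring carried the parental state in 59 of 618 chances, or 9.55% (exact two-sided binomial p = 3.95e-103 against 50%). The share was 62.5% of 24 chances at the sire's regions inside the loci and 31.8% of 66 at the dam's. The chromosome 4 gain made up 3 of those 4 regions of the sire, and 7 of the 11 of the dam lay in the chromosome 14 stretch that was low in all 8 mice. These 7 gave 17 of the 21 offspring carriers at the dam's regions inside the loci. Medians over that stretch differed little between mice, so which mice passed the threshold there is weak evidence of transmission. Outside the loci it was 4.51% of 510 chances for the dam and 0% of 18 for the sire. With runs of 5 probes in place of segments the share was 61.2% (exact p = 3.66e-08), where 89 of the 101 regions were pieces of the chromosome 4 gain. Regions close together are linked and the test counts them as separate. Of the 103 regions, 85 were regions of the dam outside the loci, and short regions followed shared profiles across mice, as given below. The 618 chances are therefore not independent, and neither p-value measures transmission.

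Offspring carried 11 regions at which both parents were under 0.15 in size, a count that was 36 with segments of at least 3 probes, 24 at a threshold of 0.2, 5 with at least 10 probes, 30 with the mouse in Cy5 only and 1 with runs of 5 probes. In 16 of the 24 undecided regions, all of them short losses, neither parent was lowered by 0.15 or more. The sire lay at 0.15 to 0.25 there and the dam at -0.11 to 0.08. The longest of the 11 was a gain on chromosome 2 from 45594154 to 45605630, which filled a tiled block of 108 probes in offspring 6. Its median was 0.30 (SD over probes 0.09), with 0.27 and 0.32 in the orientations, against -0.04 in the sire, -0.01 in the dam and -0.02 to 0.00 in the other 5 offspring. The nearest probes on either side ended at 44942778 and started at 45711139, so the ends were not resolved. The other 10 regions had 5 or 6 probes. They included losses on chromosome 7 at 90200954 to 90201145, with -0.57 in offspring 1, -0.48 in offspring 2, -0.35 in offspring 5 and -0.34 in offspring 6, and on chromosome 1 at 74427718 to 74428150, with -0.49 in offspring 1, -0.44 in offspring 2 and -0.39 in offspring 5. The sire stood at 0.12 at both. A loss of -0.41 in offspring 2 on chromosome 4 at 30872900 to 30873464 had an SD over probes of 0.24, rose to -0.08 under normexp and had no probe left without dim probes. The largest undecided regions, at 52959466 to 52959718 and 51798206 to 51798407 on chromosome 17, were carried by 4 offspring each and were at -0.78 and -0.68 in offspring 1, with the sire at 0.21 and 0.22.

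**Figure D3:**
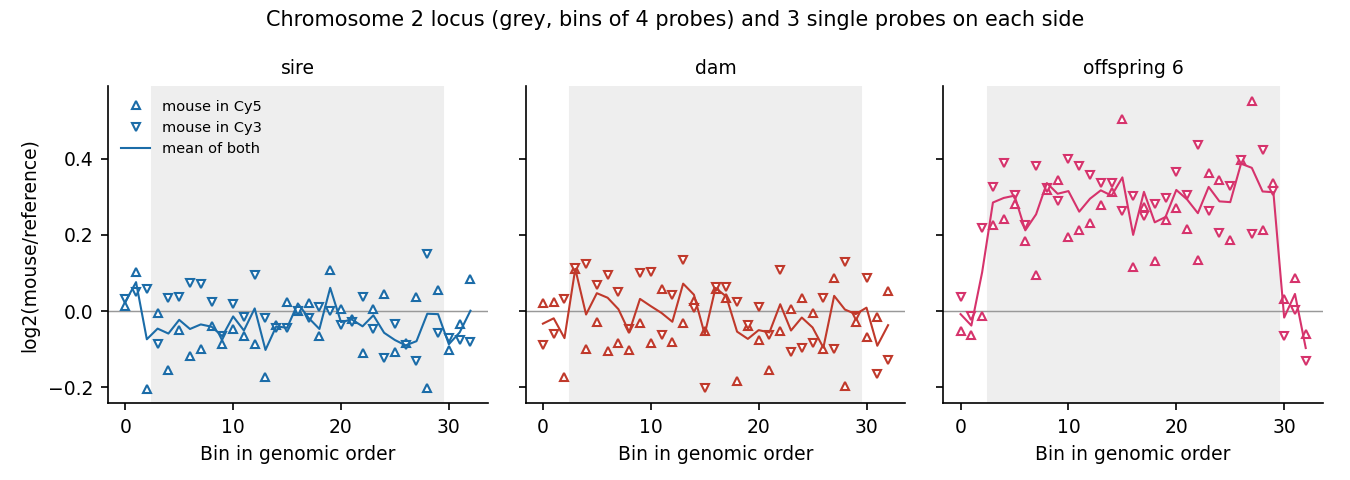
Log2(mouse/reference) in genomic order over the chromosome 2 locus (grey, 108 probes in bins of 4) and 3 isolated probes on each side, in the sire, the dam and offspring 6. Triangles are the orientations and lines their mean; offspring 6 lies near 0.30 across the block and both parents lie near 0.

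The short regions followed shared profiles across mice. At the 71 short regions carried by the dam and no offspring, the dam's mean was -0.39 ± 0.08 (SD over regions). The sire was at -0.13 ± 0.06, offspring 1 to 5 had means from -0.17 to -0.11, and offspring 6 was at 0.08 ± 0.06. At 31 regions outside the loci carried by an offspring and not by the dam, the means were -0.42 in offspring 1, -0.42 in offspring 2, -0.30 in offspring 5, -0.24 in offspring 6 and -0.15 in offspring 3, with the sire at 0.11, offspring 4 at 0.09 and the dam at -0.02. Offspring 1 and 2 shared a slide, as did 3 and 4, 5 and 6, and the parents. The means at the 31 regions, where neither parent was a carrier, followed the slides in part. Those at the 71 regions did not, with offspring 6 apart from offspring 5 and the dam, by selection, apart from the sire. Of the 205 calls outside the loci, 88 were in the dam and 0 in offspring 4.

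**Figure D4:**
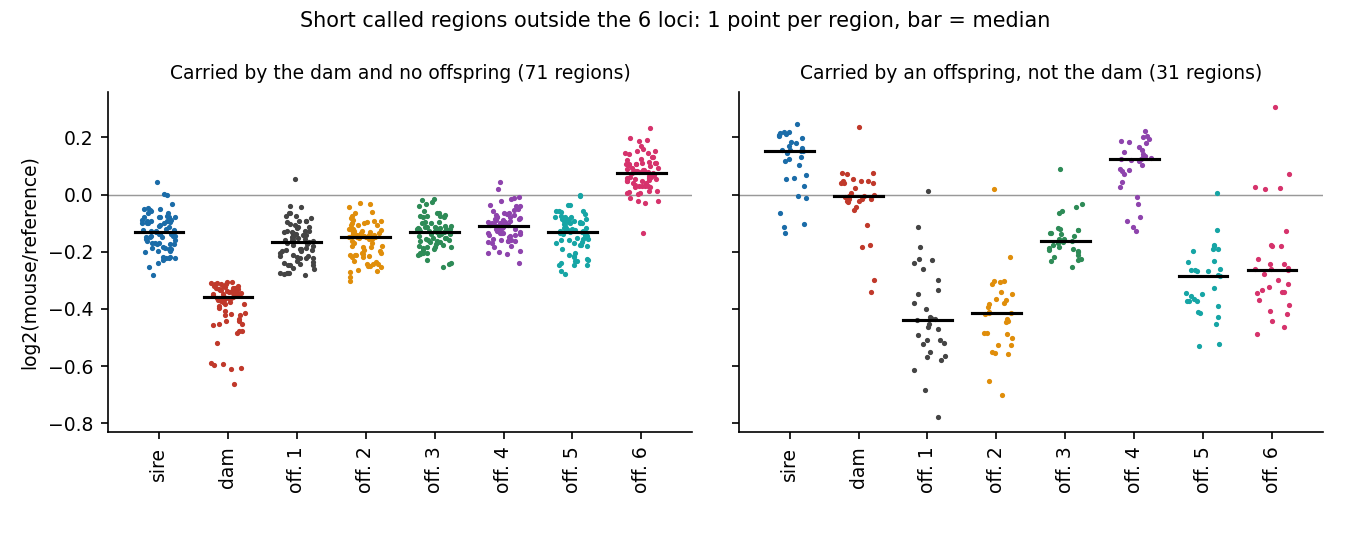
Log2(mouse/reference) of each mouse (x axis) at short called regions outside the 6 loci, 1 point per region and a bar at the median, for 71 regions carried by the dam and no offspring (left) and 31 carried by an offspring and not by the dam (right). The dam's values are at or below -0.3 by selection in the left panel, where offspring 6 lies mostly above 0.

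Another comparison set all 8 mice against the reference animal. A stretch of chromosome 14 from 53759005 to 54345205 was lower than the reference in every mouse. The same reference animal was on every array, so a shift in all mice may be its own state. Over the 14 shifted blocks and 843 probes of the stretch the medians ran from -0.27 to -0.25, with a mean of -0.26 and an SD between mice of 0.006. One copy added over 2 in every cell of the reference would give an ideal size of 0.58 with the sign turned. The carriers of the chromosome 4 gain lay at 0.50 to 0.54. The medians of the stretch argue against that state, and other states of the reference were not tested. The 15 regions called over the stretch included the 3 carried by all 8 mice. The longest of these 3, from 53698688 to 53832805, had medians of -0.37 to -0.33 over 34 probes. In limma, 2049 of 159628 probes differed from 0 in the mean of the mice (adjusted p under 0.05), 445 higher and 1604 lower. Of the 989 probes in the chromosome 14 stretch 770 were called, all of them lower, against 1132 of 156725 probes outside the 6 loci. The count was 4184 without offspring 6, 4020 without the dam, 1055 without offspring 5, 1075 without offspring 2, 1097 without offspring 3, and 6542 with arrays kept apart. Lower probes outnumbered higher ones in every setting, but by unlike margins. The split was 1902 higher and 2118 lower without the dam, and 79 higher and 976 lower without offspring 5. With arrays kept apart it was 2719 higher and 3823 lower.

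Between the offspring as a group and the parents, 0 of 159628 probes passed the adjusted threshold in limma. An unadjusted limma p under 0.05 was found at 13625 probes, a larger share than the 0.05 that no difference would give. That excess was not tested, and generation and slide cannot be separated, so small differences over many probes are not excluded. The count stayed 0 with slide as a random block, and was 5 without the sire and 1 without the dam, where the remaining parent is assumed to vary like the other mice.

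The orientations of a mouse were negatively or weakly correlated across all probes, with Pearson r from -0.49 to 0.01 and a median of -0.27, and a dye term passed the adjusted threshold in limma at 66.1% of probes. Over the 2442 probes in called regions r was 0.91 in offspring 6, 0.88 in the dam and 0.74 in the sire. It was 0.765 to 0.787 in offspring 2, 3 and 5, 0.37 in offspring 1 and -0.02 in offspring 4. A call needed the same sign in both orientations, so the agreement in called regions is set in part by the selection. It also depends on which mice carry the long regions. The chromosome 4 gain, 1337 probes when called as 1 region, was carried by the sire and offspring 2, 3, 5 and 6. Offspring 1 and 4 did not carry it, nor did the dam, which shared the deep chromosome 3 loss with offspring 6. The values of r therefore do not rank the mice by the quality of their arrays. Arrays of different mice in the same orientation correlated at 0.42 to 0.74. These correlations are across probes, which are not independent replicates.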

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

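All tests in this part were chosen after the results they bear on had been seen. Of 42 values compared over the 6 offspring, 13 had 1 offspring so far from the others that its gap to the nearest, divided by the range, passed Dixon's 95% critical value. Chance gives this in about 1 of 20 groups that were not chosen by their values. The loci and named regions were chosen for a large value in some mouse, so that rate does not hold for them. At the chromosome 2 locus offspring 6 alone reached the cut, so its departure there was set by the selection. Many of these values are also not independent.

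The deepest departures belonged to offspring 6, which lay with the dam: -1.77 at the chromosome 3 locus, 0.26 at the chromosome 8 locus, -0.27 at the chromosome 14 locus at 61810472, -0.996 at the region of 6 probes at 111694136 on chromosome 2, 0.93 over the X probes and -2.75 over the Y probes. Transmission of autosomal copies from the dam is argued against at chromosome 3, where a dam at -1.74 would leave each offspring at most the sire's copy, yet 5 offspring lay above -0.5 and the highest at 0.003. A candidate explanation is sequence that X or Y also carries. At the 3 loci of tiled blocks that the dam carried and the sire did not, offspring 6 was within 0.03 of the dam. No other offspring reached 50% of the dam's value there. Where the dam has 1 changed copy, autosomal transmission gives this in 1.56% of litters of this size per locus. That share does not hold at chromosome 3, where the dam at -1.74 was far below the level of 1 lost copy. At the region of 6 probes on chromosome 2 the difference of offspring 6 minus the dam was -0.14. It was as large in 2.51% of 24512 windows of 6 probes outside the loci and called regions. The spread of such differences at ratios as low as -0.996 was not measured, so whether the ratios are equal there stays undecided. That mapping was not tested against a genome sequence. The X and Y probes themselves set offspring 6 with the dam and apart from the other 5 in the same way, while the labels give no sex. The losses at the chromosome 3 and 14 loci had the direction of the Y probes, and the gain at chromosome 8 that of the X probes.

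Offspring 6 also stood apart at the chromosome 2 locus, with 0.30. Noise that differs between its arrays is argued against: in the difference of the orientations divided by 2, no block of this mouse exceeded 0.06 after the dye bias common to all mice was taken off, or 0.21 before. Noise shared by both arrays, as from the DNA preparation, was not tested. Sequence shared with X or Y is argued against by the dam's value of -0.007. One added copy in every cell, as on chromosome 4, would give the level seen there, but the chromosome 2 value was 0.20 lower, by 0.25 and 0.13 in the orientations. A gain in part of the cells, or an added copy of sequence with more than 2 copies in the reference, may account for the level and was not tested, and no other tissue or method was used here.

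At the short regions, offspring 6 was higher than its littermates at 149730135 on chromosome 5 (0.17), at 63643500 on chromosome 10 (0.14), at 67849404 on chromosome 11 (0.074), at 40316697 on chromosome 16 (0.23) and at 17670276 on chromosome 3 (0.15), and offspring 4 was higher at 78645428 on chromosome 17 (0.13). Copy-number states passed on by the dam were weighed at the 85 short regions that the dam carried and the sire did not. There 19.0% of offspring reached 50% of the dam's value, from 1.18% to 40.0% by offspring. The share was below 50% in 6 of 6 (exact two-sided sign test p = 0.0312, the smallest p-value that 6 offspring can give). The regions of a mouse are not independent, so the test takes the offspring as its units. Every offspring was set against the same dam values, so these units are not independent either. The regions were selected for a large value in the dam, which lowers the shares. The shares lean against transmission at all of these regions and do not decide it. A trend of the ratios with probe length is argued against as the whole cause, because the mean size at the 122 regions was 0.43 before and 0.43 after it was taken off, with no probe moved by more than 0.045. An earlier form of this test was replaced because it could exclude nothing: mean probe length was 55.9 bases over the regions and 55.3 in 10000 random draws of windows (permutation p = 0.117). At the regions carried by the dam and no offspring, 1 component held 82.1% of the variance between offspring, which restates the gap of offspring 6 there and decides no cause. The regions carried by an offspring and not the dam had another order of mice, with offspring 6 at -0.24. At those 31 regions 5 of 105 ways to pair the 8 mice, the slides included, brought them as close as the slides did. Neither parent carried any of the 31, which by itself keeps the parents, on 1 slide, close. It was 43 of 105 at the 71 regions of the dam, where the selection set the dam apart from the sire. The counts over all 8 mice therefore cannot weigh the slides. For the offspring alone it was 1 of 15 at the 31 regions and 4 of 15 at the 71. At the 31, offspring 3 at -0.15 and offspring 4 at 0.09 differed although they shared a slide. Differences in DNA preparation or hybridisation, slide included, stay open. Base composition itself could not be examined without sequence, and no biological explanation other than transmission was tested.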

How the results depend on the processing

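Of 139 alternatives to the main results, 99 left the result as it was: counts within 1.5 times, the share on the same side of its test, and the median r between orientations within 1 SD between mice. These include every normalization, although that r went from -0.27 to -0.42 under normexp. The X and Y setting, leaving out the dam for region counts, and the loci and named values were added after seeing the data. Regions called were 259 at a threshold of 0.2, 38 at 0.5, 439 with at least 3 probes, 29 with at least 10, and 73 without the dam. Carrier states were 526, 62, 926, 83 and 178 in the same order, and 509 with runs of 5 probes. Regions carried by offspring and neither parent were 24 at 0.2, 36 with 3 probes, 5 with 10 probes, 30 with the mouse in Cy5 only and 1 with runs. Regions carried by a parent and at least 1 offspring were 78 at 0.2, 7 at 0.5, 143 with 3 probes, 8 with 10 probes, 49 with the mouse in Cy3 only and 101 with runs. Those carried by a parent and no offspring were 20 at 0.5, 204 with 3 probes, 3 with 10 probes, 34 with the mouse in Cy5 only and 0 with runs. Regions carried by all 8 mice were 0 at 0.5, 1 with a penalty of 6, 0 with the mouse in Cy5 only and 1 with runs. The share of offspring carrying a 1-parent region turned from 9.55% to 61.2% with runs, where 89 of 101 regions lay in the chromosome 4 gain, and was 7.17% to 28.3% otherwise. Probes shifted in the mean of the mice numbered 1055 to 4184 when 1 mouse was left out and 6542 with arrays kept apart, and probes differing between offspring and parents 0 to 5 when 1 mouse was left out. The 6 loci were 6 under each normalization and 5 to 7 under other block rules. Of 163 values of loci and named regions under 4 normalizations, 158 moved by less than their SD over probes, and 1 turned sign, the dam at 54169067 on chromosome 14 (-0.02 under normexp). Their SDs over probes can be wide: 6 of the 35 named regions fell below 0.3 in size under normexp, 2 without dim probes, 1 with loess and 0 with the deposited value table. The cause of the other changes was not tested. Joining calls at 1 shared probe changed no count. The correction for base composition and the gene-group test with its alternatives were not run. Leaving out the 762 autosomal probes that were dim or saturated on any array moved no main count by over 1.5 times, though 1 named region then kept no probe.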

Other observations

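Of the 122 short regions, 56, or 45.9%, had their midpoint in the central 20% of their tiled block, a place that the design favours, since probes were set around candidates of the earlier screen. The blocks outside the 6 loci with the largest medians were at 97859354 to 97860146 on chromosome 6, with -0.17 in offspring 5, and at 31440371 to 31440845 on chromosome 3, with 0.15 in offspring 6. They held 12 and 10 probes.

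A hypothesis, formed and tested after the values had been seen, concerns offspring 3, whose Y probes had a median of -0.17 with an X median of 0.00. Copies that carry Y may be missing from part of its cells. A missing share of 11.1%, read from the Y probes, predicts -0.13 at the chromosome 3 region where the dam was at -2.03, and offspring 3 was observed at -0.12, which differs by 0.002. The same reckoning missed by 0.076 for offspring 3 at the region of 6 probes at 111694136 on chromosome 2, and by 0.065 for offspring 2 at the chromosome 3 region, where its Y median of -0.095 predicts -0.07 and it was at -0.01. The Y value of offspring 3 rests on 3 probes from -0.22 to -0.03 and on orientations of -0.34 and 0.00, and over 8 mice and both regions the reckoning missed by -0.51 to 0.11, with the largest misses in the dam and offspring 6, so the hypothesis stays undecided.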
